A study of Mus musculus with 6 samples.

How the data were processed

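RNA was measured on 6 Affymetrix arrays of the mouse genome, which carry short oligonucleotide probes grouped into probe sets. The samples were cultures of oligodendrocyte precursor cells, the dividing glial cells that give rise to myelinating oligodendrocytes, from the brain of C57BL6 mice at postnatal day 0. Per the labels, the cells were expanded in serum-free medium with insulin at 10 µg/ml, transferrin at 100 µg/ml, PDGF at 10 ng/ml and forskolin at 5 µM among its additives. This growth protocol is the same for all 6 arrays, FCS included, and gives no serum, so neither the amount of serum nor the time in it is known. RNA was purified on columns and labelled with biotin in a single cycle of in vitro transcription. The groups were taken from the sample titles, which name CG4, FCS and Rev with 2 arrays each, numbered 1 and 2.

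The deposited values are log2 signal intensities per probe set. The log base was inferred from the range of the values, and the authors' normalization method is not given in the sources used here. The medians of the 6 arrays lay within 0.0369 of each other on the log2 scale, under the 0.1 set for renormalization, so the deposited values were used without further scaling. The table holds 45101 probe sets, of which 64 are controls. The array annotation gives 1 gene symbol for 34958 probe sets, several for 932 and none for 9211, and names 18194 genes. Of the Entrez identifiers, those of 34754 probe sets were found in the reference gene table, and 0 symbols needed an update. That table is built on the assembly GRCm38.p6, and it served for names only.

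The choices of this paragraph, the lists and the rule for named genes were fixed before the data were examined. Control probe sets were left out. Probe sets whose mean over the 6 arrays lay under the 40th percentile of the other probe sets (log2 5.92) were left out too, which kept 27022. Each gene was then represented by its kept probe set of highest mean, among those with 1 symbol. This gave 13140 genes, 6017 of which had more than 1 kept probe set. A linear model with 1 coefficient per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual degrees of freedom, 2.61 prior degrees of freedom). The comparisons were FCS minus CG4, Rev minus CG4 and Rev minus FCS. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Values are given as mean ± SD on the log2 scale with n = 2 arrays per group, and SE is limma's moderated standard error of a log2 difference.

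A total of 24 gene lists were written for this tissue and treatment. They cover S phase, mitosis, cell cycle inhibitors, p53 targets, secreted factors of senescent cells, glial, stem cell and neuronal markers, BMP and TGF-beta response, extracellular matrix, actin and serum response, immediate early genes, cyclic AMP response, sterol and fatty acid synthesis, interferon response, antigen presentation, lysosome, and markers of microglia, endothelium, pericytes with fibroblasts, and Schwann cells. Of 720 entries 674 matched a gene on the array and 46 did not. Each list was compared with all other genes by camera from limma, with a preset correlation between genes of 0.01, adjusted over the 24 lists and 3 comparisons together. Every list call was also given with the correlation estimated from the data. That setting ended calls even where the estimated correlation lay under 0.01, so a lost call is not by itself a sign of correlated genes. Members were counted as called over all genes and as adjusted over the list alone. The named genes are the 10 highest and 10 lowest called changes of each comparison without overlap between arrays, and a fixed set of 10 genes. To these come up to 4 called members of each list (or 2 of smallest p), and the 5 largest changes per direction that were called back in Rev minus FCS. A planned group of genes called in both FCS minus CG4 and Rev minus CG4 held 0 genes. In its place stand genes that kept at least 0.75 of their FCS change in both Rev arrays, which was chosen after the data were seen.

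The share of an FCS change that was kept was the Rev array's distance from the CG4 mean divided by the FCS minus CG4 difference. A gene was counted as kept at 0.75 or more in both Rev arrays and as returned at 0.25 or less in both. Because comparisons share arrays, correlations and overlaps were set against data simulated with no group differences, in 100 draws for correlations and 10 for calls. The correlations were also computed with 1 array of the shared group in each comparison, which was added after the data were seen. The whole procedure was tested on simulated data of the same 13140 genes for FCS minus CG4. It called 33 of 100 genes with a log2 change of 1 and 98 of 100 with a log2 change of 2, with 0 in the wrong direction and 7 false calls. In the same data 0 genes were called in the unchanged Rev minus CG4 comparison, and the raised list was called in 2 of 2 tests against 0 of 70 other tests. The simulated genes varied independently, so the 0 of 70 does not bear on false calls of lists whose genes move together.

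Alternatives covered quantile normalization, centring on the median, no filter and a filter at the 60th percentile, means over probe sets, probe sets on their own, trend and robust variance models, fits of 4 arrays, a block for replicate number, stricter thresholds, other set tests (fry) and leaving out each array. Array weights, a block with the Rev numbers crossed and counts without cell cycle genes were added after the data were seen. So were the counts of list members in the fit of 4 arrays, of named genes called with each array left out, and of unadjusted p-values under each alternative. Alternatives to a pseudocount were not run, since the values are already logarithms. The labels do not say that the array numbers mark a shared preparation, and nothing in them says that replicates came from separate cultures, so the p-values measure only the spread between these samples. For arrays there is no count of molecules behind a value, and their number limits the precision. Figures were drawn with matplotlib 3.10.9.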

Results

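Transcript levels were measured on 6 arrays of cultured mouse oligodendrocyte precursor cells. The titles place 2 arrays in each of 3 groups, CG4, FCS and Rev. According to the series, such cells turn senescent when grown with much fetal calf serum (FCS), and the comparison of interest is what they keep once the serum is taken away. The labels do not spell out the abbreviations CG4 and Rev, so the groups are named here by their labels. The growth protocol gives all 6 arrays the same serum-free medium, so that the FCS cells had serum is read from their title and the series alone. Array medians lay between 6.54 and 6.58 on the log2 scale. Across the 45037 probe sets that are not controls, the paired arrays of a group correlated at 0.992 in CG4, 0.993 in FCS and 0.984 in Rev (Pearson). Probe sets are not independent replicates. The Rev arrays stood farther apart than the other pairs, with 903 genes differing more than 2-fold between them against 279 in CG4 and 352 in FCS.

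The FCS minus CG4 comparison asks what serum does to the transcripts of these precursor cells. Ecrg4, which encodes a secreted protein tied to growth arrest, stood at 12.95 ± 0.19 in FCS and 7.89 ± 0.78 in CG4 (mean ± SD, n = 2 each). That is a log2 change of 5.06 (SE 0.40), or 33.4-fold (adjusted p = 0.00385, higher in both FCS arrays). Genes of the actin cytoskeleton and of the BMP and TGF-beta response rose by a median of 1.80 and 1.88, and the interferon response list rose by a median of 0.92. The lists for S phase, mitosis and oligodendrocyte precursor markers fell, with medians of -1.84, -2.19 and -1.27, although 0 of 28, 1 of 31 and 6 of 27 members were called over all genes. None of these 6 list calls held with an estimated correlation, where the adjusted p = 0.239 for BMP and TGF-beta response, 0.488 for interferon, 0.527 for actin, 0.643 for precursor markers, 0.670 for S phase and 0.687 for mitosis. In all, 1739 of 13140 genes were called, 1008 higher and 731 lower in FCS, of which 740 and 397 changed at least 2-fold. This balance is uncertain, since over all genes whose arrays do not overlap 3846 were higher and 4711 lower (65.1% of genes, chance 33.3%).

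The largest rise was that of Npvf, which encodes an RF-amide neuropeptide, from 7.01 ± 0.22 in CG4 to 13.03 ± 0.55 in FCS (log2 change 6.02, SE 0.62, adjusted p = 0.00605). Next came Tmem163, a zinc transporter, with 5.97 (adjusted p = 0.00593), and Cemip, which degrades hyaluronan, with 5.69. Ahnak, a giant scaffold protein, rose by 5.67, the membrane peptidase Mme by 5.18, the matrix proteoglycan Ogn by 5.17, the growth factor Pdgfd by 5.12, the organic anion transporter Slco1a4 by 5.04 and Ccn2, a matrix protein induced by TGF-beta, by 4.99. Among the lowest, the Notch ligand Dll3 changed by -5.07, the Notch feedback regulator Nrarp by -4.88, secretogranin Scg2 by -4.86 and the carbonic anhydrase Car3 by -4.81. Nxph1 changed by -4.75, the glutamate receptor Grm3 by -4.67, Prr18 by -4.44, the Notch target Hes5 by -4.41, Lrrn1 by -4.20 and Nnat by -4.16. Adjusted p-values of these 10 lower genes ran from 0.00272 for Prr18 to 0.0280 for Scg2. Both further probe sets of Ecrg4 were higher in FCS as well, by 4.52 and 2.37, and those of Ogn by 3.12 and of Hes5 by -4.16 followed their genes. The further probe sets of Ahnak with -0.27 (adjusted p = 0.386) and of Cemip with 0.11 (0.653) did not, nor did that of Fosl2 with 0.10, not called, so the changes of these 3 genes each rest on 1 probe set. Of 40 called genes named here that have further probe sets over the filter, 10 had none that passed in the same direction, among them also Ccnd3, Ctsl, Erap1, Mvd, Mybl2, Pde10a and Sox3. Of 95 called genes named here, 15 had 1 group mean under the filter value of 5.92, where the signal may not exceed background, so the size and rank of their changes are uncertain. They are Tmem163, Cemip, Mme, Ogn, Pdgfd, Perp, Nrg1, Tbx2, Smad6, Nog and Klf2, low in CG4, and Nxph1, Grm3, Mybl2 and Lama1, low in FCS.

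Among regulators of the cell cycle, Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose from 13.06 ± 0.03 to 13.91 ± 0.04 (log2 change 0.85, SE 0.15, adjusted p = 0.0224). Cyclin D3 (Ccnd3) rose by 0.74 (adjusted p = 0.0336). Cdkn2b (p15) differed by 0.97 (adjusted p = 0.0973), Cdkn2a (p16 and p19) by 0.19 (0.644), Ccnd1 by 0.28 (0.671) and Ccnd2 by 0.36 (0.168), none of them called. For Ccnd2 the result depended on the probe set. Further ones were higher in FCS by 1.13 (adjusted p = 0.0206 in limma) and 0.87 (0.0373), while the rest, at 0.24 to 0.62, did not pass. In the list of cell cycle inhibitors and senescence markers 6 of 26 members rose, 3 fell and 17 were not called, and adjusted over the list alone 6 rose and 4 fell. Besides Ecrg4 its largest called changes were Id1 with 3.27, Ezh2 with -2.18 and Tbx2 with 2.07. As a group the list was not called (median 0.18, adjusted p = 0.312). Of 28 p53 targets 7 rose, 1 fell and 20 were not called, and adjusted over the list alone the counts were 7 and 1. Perp rose by 3.42, Gadd45a by 2.69 and the death receptor Fas by 1.70, while Ddit4 fell by 2.04. The list rose as a group (median 0.34, adjusted p = 0.000458; adjusted p = 0.488 with an estimated correlation). Of 30 secreted factors of senescent cells 5 rose, 1 fell and 24 were not called, with 6 and 1 adjusted over the list alone. Csf1 rose by 2.55, Nrg1 by 1.95, Timp2 by 1.73 and Cxcl10 by 1.43. The group's median was 0.27 (adjusted p = 0.00444; adjusted p = 0.488 with an estimated correlation).

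All 28 measured S phase genes and all 31 mitosis genes had lower means in FCS. The S phase list fell by a median of 1.84 (adjusted p = 5.37e-07; adjusted p = 0.670 with an estimated correlation) and the mitosis list fell by 2.19 (adjusted p = 4.78e-06; adjusted p = 0.687 with an estimated correlation). Of the S phase genes 0 were called over all genes, against 20 lower at an unadjusted p under 0.05 in limma and 14 lower adjusted over the list alone. Its smallest p-values were those of Pole with -2.06 (adjusted p = 0.0511) and Gins1 with -2.36 (0.0515). Of the mitosis genes 1 fell and 30 were not called, with 1 adjusted over the list alone. That gene was Mybl2, a transcription factor of the cell cycle, which fell by 0.99 (adjusted p = 0.0136), and the next was Ndc80 with -1.75 (0.0584). Mki67, the Ki-67 proliferation antigen, stood at 9.03 ± 1.07 in FCS and 11.31 ± 0.07 in CG4 (log2 difference -2.28, adjusted p = 0.195). The spread of these genes came largely from the Rev arrays. A fit of the 4 CG4 and FCS arrays alone called 27 of 28 S phase genes and 23 of 31 mitosis genes lower, and it called Mki67 (adjusted p = 0.0348).

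Of 31 genes of actin cytoskeleton and serum response 18 rose, 1 fell and 12 were not called, and adjusted over the list alone 28 rose and 1 fell. Ccn2 rose by 4.99, the matrix glycoprotein Thbs1 by 4.53, the annexin Anxa1 by 3.70 and Ccn1 by 3.35, and Tagln2 was the member that fell. The group test gave an adjusted p of 9.13e-12 (adjusted p = 0.527 with an estimated correlation). Of 21 genes of BMP and TGF-beta response 11 rose, 0 fell and 10 were not called, with 15 higher adjusted over the list alone. Smad6, an inhibitor induced by BMP signalling, rose by 4.27, its fellow target Id1 by 3.27 and the BMP antagonist Nog by 2.25 (list adjusted p = 3.65e-10; adjusted p = 0.239 with an estimated correlation). Of 36 extracellular matrix genes 7 rose, 1 fell and 28 were not called, and adjusted over the list alone 10 rose and 3 fell. Collagen Col8a1 rose by 3.75, fibronectin (Fn1) by 3.10 and Nid2 by 2.74 (list median 0.40, adjusted p = 0.00254; adjusted p = 0.643 with an estimated correlation). Markers of pericytes and fibroblasts moved in part with these groups. Of 11 such markers 3 rose, 0 fell and 8 were not called, with 3 higher and 1 lower adjusted over the list alone. Ogn rose by 5.17, Pdgfrl by 2.50 and Foxc1 by 1.35, and the group was not called (median 0.15, adjusted p = 0.178).

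Of 27 interferon response genes 14 rose, 1 fell and 12 were not called, and adjusted over the list alone 16 rose and 1 fell. The antiviral membrane protein Ifitm2 rose by 4.05, Samd9l by 2.99, the RNA sensor Ifih1 by 2.54 and Ifi27 by 2.46, while the guanylate-binding protein Gbp3 fell. The list rose as a group (median 0.92, adjusted p = 4.33e-06; adjusted p = 0.488 with an estimated correlation). In antigen presentation 4 of 17 genes rose, 1 fell and 12 were not called, with the counts 4 and 1 adjusted over the list alone. The peptide transporter Tap2 rose by 1.58, Tapbp by 1.32, the class I gene H2-D1 by 1.30 and Erap1 by 0.90 (list median 0.30, adjusted p = 0.0102; adjusted p = 0.622 with an estimated correlation). Of 30 lysosomal genes 3 rose, 0 fell and 27 were not called, with 3 adjusted over the list alone. They were the proteases Lgmn with 1.73, Ctsl with 1.18 and Ctsd, which reached 13.59 ± 0.05 from 12.59 ± 0.17 (list median 0.52, adjusted p = 0.000325; adjusted p = 0.527 with an estimated correlation).

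Of 27 oligodendrocyte precursor markers 6 fell, 0 rose and 21 were not called, with 8 lower adjusted over the list alone. The proteoglycan Vcan changed by -1.94, the lineage transcription factor Olig2 by -1.89, Sox8 by -1.73 and Tmem100 by -1.51. The list fell as a group (adjusted p = 0.000107; adjusted p = 0.643 with an estimated correlation). Pdgfra, the PDGF receptor of these cells, stood at 7.32 ± 0.51 in FCS and 9.74 ± 0.10 in CG4 (log2 difference -2.42, adjusted p = 0.121). Gfap, the intermediate filament of astrocytes, stood at 10.46 ± 0.86 and 8.07 ± 0.87 (log2 difference 2.38, adjusted p = 0.107). The fit of 4 arrays called both Pdgfra (adjusted p = 0.00720) and Gfap (0.0421). The other lineage lists were not called as groups. Of 20 myelinating oligodendrocyte markers 1 rose and 2 fell, both over all genes and adjusted over the list alone (median -0.14, adjusted p = 0.322), with Bcas1 at -3.37, Nfasc at 2.16 and the myelin enzyme Cnp at -0.91. Of 28 astrocyte markers 1 rose and 2 fell, and 4 and 2 adjusted over the list alone (median 0.20, adjusted p = 0.438), with the retinal dehydrogenase Aldh1a1 at 3.55, Aldh1l1 at -2.03 and Fabp7 at -0.60. Of 21 neural stem cell markers 3 rose and 7 fell, and 6 and 8 adjusted over the list alone (median -0.11, adjusted p = 0.237), with Sox11 at -2.62, Sox3 at -2.61 and the receptor Egfr at -2.33. Of 18 neuron markers 1 rose and 5 fell, and 2 and 5 adjusted over the list alone (median -0.31, adjusted p = 0.232). Reelin (Reln) rose by 3.07, and the growth cone protein Gap43 changed by -1.94 and Ina by -1.77.

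The remaining lists were not called as groups either. Of 31 immediate early genes 4 rose and 1 fell, and 5 and 1 adjusted over the list alone (median 0.36, adjusted p = 0.128), with Fosl2 at 3.21, Dusp1 at 2.24, Atf3 at 1.98 and Klf2 at 1.97. Of 21 cyclic AMP response genes 2 rose and 2 fell, the same counts adjusted over the list alone (median -0.07, adjusted p = 0.727), with Rgs2 at 2.03 and Pde7b at -1.37. Of 21 sterol synthesis genes 1 rose and 3 fell, and 1 and 4 adjusted over the list alone (median -0.38, adjusted p = 0.143), with Dhcr7 at -1.59 and Mvd at -1.36. Of 22 fatty acid synthesis genes 1 rose and 3 fell, and the same adjusted over the list alone (median -0.09, adjusted p = 0.244), with Fads3 at 2.67, Elovl6 at -1.54 and fatty acid synthase (Fasn) at -0.97. Among markers of other cells, 1 of 8 microglia genes rose, and 1 adjusted over the list alone (Lyz2 with 1.01, median 0.02, adjusted p = 0.716). Likewise 1 of 8 endothelial genes rose, and 1 adjusted over the list alone (Slco1a4, median 0.03, adjusted p = 0.681). Of 12 Schwann cell markers 2 rose, with 2 higher and 1 lower adjusted over the list alone (median 0.11, adjusted p = 0.371). They were the small heat shock protein Cryab with 4.46 and Pmp22 with 2.05.

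The count of called genes depended on each array. It was 304 without CG4 1, 268 without CG4 2, 458 without FCS 1, 263 without FCS 2, 2715 without Rev 1 and 2712 without Rev 2. Of 95 called genes named here 22 were called in all 6 of these fits, Ecrg4, Ccn2, Smad6, Thbs1, Ifitm2, Csf1, Olig2, Vcan and Hes5 among them. Cdkn1a was called in 2 of the 6 and Npvf in 3. The share of calls that were higher in FCS was 58.0% with all arrays and ran from 49.8% without Rev 2 to 75.3% without FCS 2. For Ecrg4 the adjusted p lay between 0.00373 and 0.0394.

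**Figure D1:**
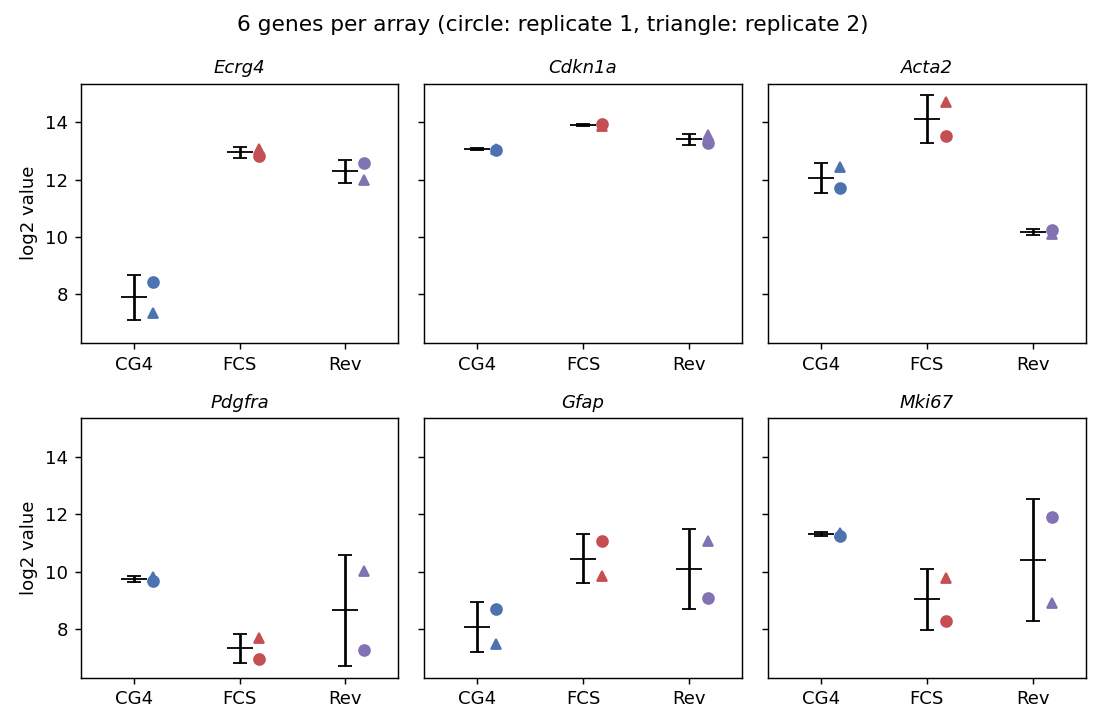
Log2 signal (vertical axis) of Ecrg4, Cdkn1a, Acta2, Pdgfra, Gfap and Mki67 in each array by group, with circles for array 1, triangles for array 2 and bars for the mean ± SD of 2 arrays. Ecrg4 lies near 7.89 in CG4, 12.95 in FCS and 12.28 in Rev, whereas Mki67 and Pdgfra lie far apart between the Rev arrays.

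The Rev minus CG4 comparison asks what still differs from CG4 in the cells labelled Rev. Ecrg4 stood at 12.28 ± 0.40 in Rev (n = 2), a log2 difference of 4.40 (SE 0.40), or 21.1-fold, with both Rev arrays over both CG4 arrays. Its adjusted p of 0.0696 missed the threshold, as did that of each of the 13140 genes. The interferon response, p53 target, astrocyte, antigen presentation and lysosome lists rose as groups, and the S phase, mitosis, sterol synthesis and neural stem cell lists fell. None of these 9 list calls held with an estimated correlation (adjusted p from 0.435 for interferon to 0.803 for mitosis), and the S phase and mitosis lists were low in Rev 2 alone, with means against CG4 of 0.03 and 0.42 in Rev 1. In limma 0 genes were called, while 1637 had an unadjusted p under 0.05 where chance gives 657.

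Of 27 interferon response genes 20 had higher means in Rev, 0 were called over all genes and 12 were higher adjusted over the list alone. Trim30a differed by 1.93 and the interferon-induced protease Usp18 by 1.54 (adjusted p = 0.0696 each). In both Rev arrays these genes lay above their FCS mean. The list rose by a median of 0.75 (adjusted p = 1.06e-08; adjusted p = 0.435 with an estimated correlation). Against the CG4 mean the list lay at 0.87 and 0.88 in the Rev arrays and at 1.09 and 1.06 in the FCS arrays. The p53 targets rose by a median of 0.28 (adjusted p = 0.00217; adjusted p = 0.488 with an estimated correlation), with 0 members called and 2 higher adjusted over the list alone. They include Sesn1 with 0.96 and Mdm2 with 0.68. Antigen presentation genes rose by a median of 0.24 (adjusted p = 0.0104; adjusted p = 0.622 with an estimated correlation), with 0 called, 1 higher adjusted over the list alone and H2-D1 at 0.91. Lysosomal genes rose by a median of 0.31 (adjusted p = 0.000229; adjusted p = 0.527 with an estimated correlation). Of these 26 of 30 had higher means, with 0 called and 0 adjusted over the list alone, Tpp1 at 0.75 and Ctsl at 0.61. Astrocyte markers rose by a median of 0.45 (adjusted p = 0.00580; adjusted p = 0.747 with an estimated correlation). Of these 23 of 28 had higher means, 0 were called and 1 was higher adjusted over the list alone, with Aldh1a1 at 3.92 and Aldh1l1 at -1.68.

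Sterol synthesis genes fell by a median of 0.72 (adjusted p = 4.78e-06; adjusted p = 0.658 with an estimated correlation). Of these 18 of 21 had lower means, 0 were called and 6 were lower adjusted over the list alone, with Dhcr7 at -1.22 and Pmvk at -0.73. The list averaged 0.26 and -0.26 in the CG4 arrays and -0.36 and -0.82 in the Rev arrays, so CG4 2 lay near Rev 1. Neural stem cell markers fell by a median of 0.18 (adjusted p = 0.0104; adjusted p = 0.488 with an estimated correlation), with 0 called and 3 lower adjusted over the list alone. Hes5 differed by -1.53 and the tetraspanin Cd9 by -1.06. The S phase list fell by a median of 0.88 (adjusted p = 7.50e-06; adjusted p = 0.686 with an estimated correlation) and the mitosis list fell by 0.90 (adjusted p = 0.000728; adjusted p = 0.803 with an estimated correlation), each with 0 called and 0 adjusted over the list alone. Gins1 differed by -1.15, E2f2 by -1.03, Mybl2 by -0.51 and Cdca8 by -1.38. These 2 lists divided the Rev arrays. Against the CG4 mean, S phase genes averaged 0.03 in Rev 1 and -1.89 in Rev 2, and mitosis genes 0.42 and -2.23. Without Rev 2 the S phase median was -0.02 (adjusted p = 0.977) and the mitosis median 0.46 (0.0454), and without Rev 1 they were -1.65 and -2.34. Mki67 stood at 11.91 in Rev 1 and 8.89 in Rev 2, and Pdgfra at 7.28 and 10.02.

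Other list calls also rested on single arrays. The astrocyte call ended without CG4 2 (adjusted p = 0.111) and without Rev 2 (0.394), the antigen presentation call without CG4 2 (0.0692) and without Rev 1 (0.127), and the p53 and neural stem cell calls without Rev 1 (0.148 and 0.214). Of the fixed genes, Gfap was 4.01-fold higher (adjusted p = 0.398), Pdgfra by -1.09 (0.632), Mki67 by -0.90 (0.740), Cdkn1a by 0.36 (0.415), Ccnd3 by 0.10 (0.809), Ccnd1 by 0.01 (0.994), Ccnd2 by -0.08 (0.841), Cdkn2a by -0.13 (0.845) and Cdkn2b by 0.00 (0.997).

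Several lists called in FCS minus CG4 were not called in Rev minus CG4. The BMP and TGF-beta response had a median of 0.13 (adjusted p = 0.663), the actin and serum response 0.17 (0.196), the extracellular matrix -0.01 (0.681), secreted factors of senescent cells 0.05 (0.159) and oligodendrocyte precursor markers -0.19 (0.178). Among their members, none called, Ccn2 had 1.89 (adjusted p = 0.169), Csf1 0.80 (0.169) and Smad6 0.89 (0.229), and Tagln2 had -2.19 (0.0696). The other 10 lists were not called, with medians of -0.13 for cell cycle inhibitors, 0.03 for myelinating oligodendrocytes, 0.16 for immediate early genes, 0.11 for cyclic AMP response and 0.01 for fatty acid synthesis. Those of other cells were -0.19 for neurons, 0.03 for microglia, -0.06 for endothelium, 0.13 for pericytes and fibroblasts and 0.09 for Schwann cells. Adjusted p-values of these 10 lists ran from 0.178 for neurons to 0.902 for microglia. Adjusted over the list alone, 3 cell cycle inhibitors were higher, 3 actin and serum response genes higher and 2 lower, and 1 neuron marker higher and 2 lower. A single gene was higher in each of the secreted factors, myelinating oligodendrocyte, BMP and TGF-beta, endothelial and pericyte lists, and 0 passed in the others of these lists.

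Changes in Rev ran along those in FCS. Across the 13140 genes, FCS minus CG4 and Rev minus CG4 correlated at 0.716 (Spearman 0.686), where simulated groups without differences that share the CG4 arrays gave 0.497. The covariance was 0.258 against 0.0346 simulated, and part of the excess in correlation may still come from the shared arrays. With 1 CG4 array in each comparison, so that none was shared, the correlations were 0.465 and 0.686 and the covariances 0.203 and 0.246. Of the 1739 genes called in FCS minus CG4, 1608 (92.5%) differed in the same direction in Rev minus CG4, where data simulated with Rev equal to CG4 gave 59.2%. The median share of the FCS change found in Rev was 0.401 (quartiles 0.215 and 0.561). At least 0.75 of it was kept in both Rev arrays by 87 genes (5.00%), against 0.577% in data simulated with Rev equal to CG4 and 65.8% with Rev equal to FCS. At most 0.25 was left in both arrays for 327 genes (18.8%), against 65.8% in data simulated with Rev equal to CG4 and 0.546% with Rev equal to FCS, and 1325 lay between or differed by array. The simulated shares are of 3674 genes called in FCS minus CG4 with Rev equal to CG4 and of 3663 with Rev equal to FCS, about 2 times the 1739 of the data, and in the first 3000.5 were called back against 342. The simulated data thus hold more calls than were observed, and their shares are only rough limits. Kept genes included Ecrg4, Aldh1a1 with 3.55 in FCS and 3.92 in Rev, Samd9l with 2.99 and 2.49, Ifi27 with 2.46 and 2.39, and Trim34a with 2.19 in FCS. On the lower side they included Fndc3c1 with -3.64 in FCS and -3.58 in Rev, Rab3b with -2.32 in FCS, the laminin chain Lama1 with -2.08, Gap43 with -1.94 and -2.12, and Mamdc2 with -1.94. A test chosen after these values were seen adjusted the Rev minus CG4 p-values over the 1739 genes alone. It called 410 genes, 270 higher and 140 lower, 409 of them in the direction of the FCS change, against 0.2 in simulated data with Rev equal to CG4. The 1739 genes were selected with the same CG4 arrays, whose errors push both differences the same way, so 410 may be too high. The 0.2 comes from the simulated data with about 2 times the calls and is only a rough limit.

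**Figure D2:**
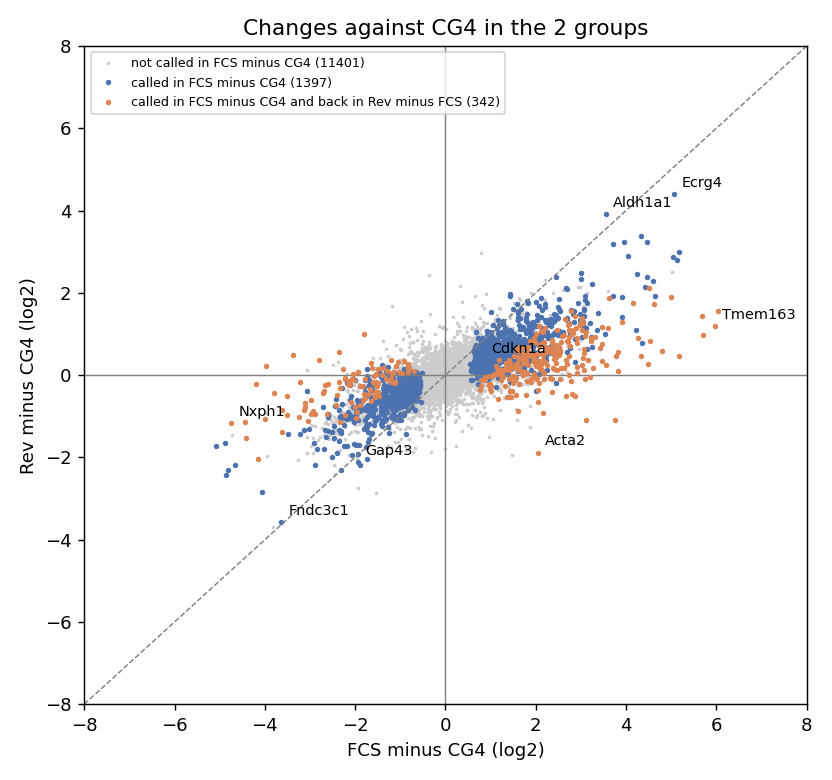
Log2 difference of FCS minus CG4 (horizontal axis) against Rev minus CG4 (vertical axis) for 13140 genes, with 11401 not called in FCS minus CG4, 1397 called in it alone and 342 called back in Rev minus FCS marked by colour, and a dashed line where both are equal. Ecrg4, Aldh1a1 and Fndc3c1 lie near the line, while Tmem163, Nxph1 and Acta2 lie far from it.

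The Rev minus FCS comparison asks what differs from the serum-treated cells in the cells labelled Rev. The actin and BMP response genes fell back, with medians of -1.51 and -1.86, and precursor markers rose by a median of 0.67, with 3 of 27 members called and list means against CG4 of -0.81 in Rev 1 and 0.31 in Rev 2. None of these 3 list calls held with an estimated correlation (adjusted p = 0.488 for actin, 0.239 for BMP and 0.643 for precursor markers). Ecrg4 differed by -0.66 (SE 0.40, adjusted p = 0.455), so that no fall was detected with 2 arrays per group. A fit of only the 4 FCS and Rev arrays called 62 genes. In limma with all 6 arrays 355 genes were called, 106 higher and 249 lower in Rev. This balance is uncertain, since over all genes whose arrays do not overlap 3615 were higher and 2881 lower (49.4% of genes, chance 33.3%). Of these 342 (96.3%) had been called in the opposite direction in FCS minus CG4, 241 higher in FCS and 101 lower, and are described as called back. Independent lists of these sizes would share 19.1 and 5.90 genes in those directions, and simulated groups without differences shared 0.1. Neither number is a bound for comparisons that share the FCS arrays, since the first leaves out the sharing and the second holds almost no calls. Across genes FCS minus CG4 and Rev minus FCS correlated at -0.845, against -0.503 in simulated groups without differences, and at -0.680 and -0.765 with 1 FCS array in each comparison.

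The largest rises were Lpo, a peroxidase, with 4.19 (SE 0.39, adjusted p = 0.0152), Lrrn1 with 3.98, the oligodendrocyte protein Bcas1 with 3.86, Nxph1 with 3.58 and Gatm, an enzyme of creatine synthesis, with 3.38. They were followed by Prr18 with 3.31 (adjusted p = 0.0120), the myelin glycoprotein Omg with 3.15, the Wnt receptor Fzd9 with 3.05, Lmo3 with 3.02 and Wscd1 with 2.91. In the other direction Col8a1 changed by -4.83, Tmem163 by -4.78, Cemip by -4.73, Mme by -4.72 and Npvf by -4.47. Ahnak changed by -4.23, Coch by -4.21, Anxa3 by -4.20, the small heat shock protein Hspb8 by -4.19 and smooth muscle actin (Acta2) by -3.93. Of the 342 genes that were called back, the largest FCS changes were those of Npvf, Tmem163, Cemip, Ahnak and Mme upward and of Nxph1, Prr18, Hes5, Lrrn1 and Nnat downward. Nxph1 in FCS and Coch, Prom1 and Smad6 in Rev lay under the filter value of 5.92, so the size of these 4 changes is uncertain. Of 20 called genes named here with further probe sets over the filter, 6 had none that passed in the same direction, namely Ahnak, Cemip, Acta2, Hes5, Wscd1 and Fosl2, whose further probe set differed by -0.28 (adjusted p = 0.483). None of the fixed genes was called. Cdkn2b differed by -0.97 (adjusted p = 0.186), Ccnd3 by -0.64 (0.104), Ccnd2 by -0.44 (0.201), Cdkn2a by -0.32 (0.550), Ccnd1 by -0.27 (0.769), Gfap by -0.38 (0.848), Pdgfra by 1.33 (0.487) and Mki67 by 1.38 (0.548), and Cdkn1a was 1.41-fold lower (0.170).

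Of 31 genes of actin and serum response 10 fell, 0 rose and 21 were not called, with 21 lower adjusted over the list alone. Anxa3 and Acta2 led, followed by Thbs1 with -3.69 and the smooth muscle protein Tagln with -3.41 (list adjusted p = 7.50e-17; adjusted p = 0.488 with an estimated correlation). Of 21 genes of BMP and TGF-beta response 10 fell, 0 rose and 11 were not called, with 15 lower adjusted over the list alone. Smad6 changed by -3.38, Id1 by -3.11, Ccn2 by -3.11 and the activin antagonist Fst by -2.71 (list adjusted p = 4.11e-15; adjusted p = 0.239 with an estimated correlation). Of 36 matrix genes 4 fell, 0 rose and 32 were not called, with 10 lower adjusted over the list alone. Besides Col8a1 and Thbs1 they were Fn1 with -3.19 and Nid2 with -2.29 (list median -0.44, adjusted p = 9.05e-06; adjusted p = 0.587 with an estimated correlation). Among secreted factors of senescent cells 2 of 30 fell and 0 rose, with 5 lower and 1 higher adjusted over the list alone. Csf1 fell by 1.75 and Cxcl10 fell by 1.24 (list median -0.15, adjusted p = 0.00724; adjusted p = 0.488 with an estimated correlation). Of 28 p53 targets 1 fell, Perp by 2.75, with 1 adjusted over the list alone (list median -0.16, adjusted p = 0.0170; adjusted p = 0.544 with an estimated correlation).

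Of 27 oligodendrocyte precursor markers 3 rose, 0 fell and 24 were not called, with 7 higher and 1 lower adjusted over the list alone. Vcan rose by 2.02, Olig2 by 1.63 and Epn2 by 1.22 (list adjusted p = 0.000229; adjusted p = 0.643 with an estimated correlation). The S phase list rose by a median of 0.84 (adjusted p = 0.000794; adjusted p = 0.803 with an estimated correlation) and the mitosis list by 1.22 (adjusted p = 0.000604; adjusted p = 0.803 with an estimated correlation). Each had 0 members called over all genes and 0 adjusted over the list alone, with Pole at 1.54, Rfc4 at 1.37, Ndc80 at 1.27 and Mybl2 at 0.49. These groups again followed the division of the Rev arrays. Without Rev 1 the S phase median was -0.09 (adjusted p = 0.563) and the mitosis median -0.21 (0.550), and without FCS 1 both calls ended (0.0821 and 0.181). The precursor list had an adjusted p of 0.106 without Rev 2, with means against CG4 of -0.81 in Rev 1 and 0.31 in Rev 2. The p53 call ended without FCS 1 (0.0787) and without Rev 2 (0.213), and with a filter at the 60th percentile the p53 and secreted factor calls had adjusted p-values of 0.0656 and 0.0555.

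The interferon response differed by a median of -0.07 between Rev and FCS over all 27 members and was not called (adjusted p = 0.178), with 0 of 27 genes called and 0 adjusted over the list alone. Of the 14 members that rose in FCS, however, 6 were lower in Rev at an unadjusted p under 0.05 in limma. Over all 27 members 4 were higher and 7 lower in Rev at that threshold. The other 15 lists were not called either. Neural stem cell markers had 3 higher and 1 lower, and 6 and 5 adjusted over the list alone (median 0.05, adjusted p = 0.681), with Hes5 at 2.89, Egfr at 2.02, Prom1 at -1.98 and Sox11 at 1.67. Myelinating oligodendrocyte markers had 2 higher, Bcas1 and Cnp with 1.24, and 2 and 1 lower adjusted over the list alone (median 0.10, adjusted p = 0.194). Of the fatty acid genes Srebf1 rose by 1.04 and Fads3 fell by 2.30, and 5 and 1 passed adjusted over the list alone (median 0.20, adjusted p = 0.0734). Single falls were those of Id1 among cell cycle inhibitors, Fosl2 with -3.26 among immediate early genes, Rgs2 with -1.80 in cyclic AMP response, Tap2 with -0.99 in antigen presentation, the tubulin Tubb3 with -1.24 among neuron markers and Pmp22 with -1.54 among Schwann cell markers. Their list medians were -0.24, -0.20, 0.11, -0.10, 0.12 and 0.11, with adjusted p-values from 0.123 for antigen presentation to 0.716 for neurons and Schwann cells. Sterol synthesis (median -0.24, adjusted p = 0.0781), lysosome (-0.11, 0.0926), astrocyte (0.24, 0.244), microglia (0.00, 0.696), endothelial (0.00, 0.371) and pericyte and fibroblast (-0.01, 0.204) lists had 0 called genes. For Aldoc and Ogn this depended on the probe set. Further ones differed by 3.45 for Aldoc (adjusted p = 0.0241 in limma) and -1.77 for Ogn (0.0349), while those of Gfap did not pass. Adjusted over the list alone, 5 immediate early genes, 2 endothelial and 3 pericyte and fibroblast genes were lower, as were 1 cyclic AMP response and 1 antigen presentation gene. Neuron markers had 2 higher and 2 lower, cell cycle inhibitors and Schwann cell markers 1 higher and 1 lower each, and the sterol, lysosome, astrocyte and microglia lists 0. The median and the group test differed in sign here for endothelial, microglia and Schwann cell markers, as did the mean for Schwann cell markers. For endothelial markers in Rev minus CG4 the mean of 0.21 differed in sign from both the median and the test.

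The 355 calls became 65 without CG4 1, 64 without CG4 2, 3 without FCS 1, 0 without FCS 2, 231 without Rev 1 and 556 without Rev 2. Of these calls 47.1% were higher without Rev 2, against 29.9% with all arrays. Without FCS 2, where limma called 0, 1317 genes had an unadjusted p under 0.05, and the 342 genes called back became 55, 61, 3, 0, 224 and 517 in the same order.

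**Figure D3:**
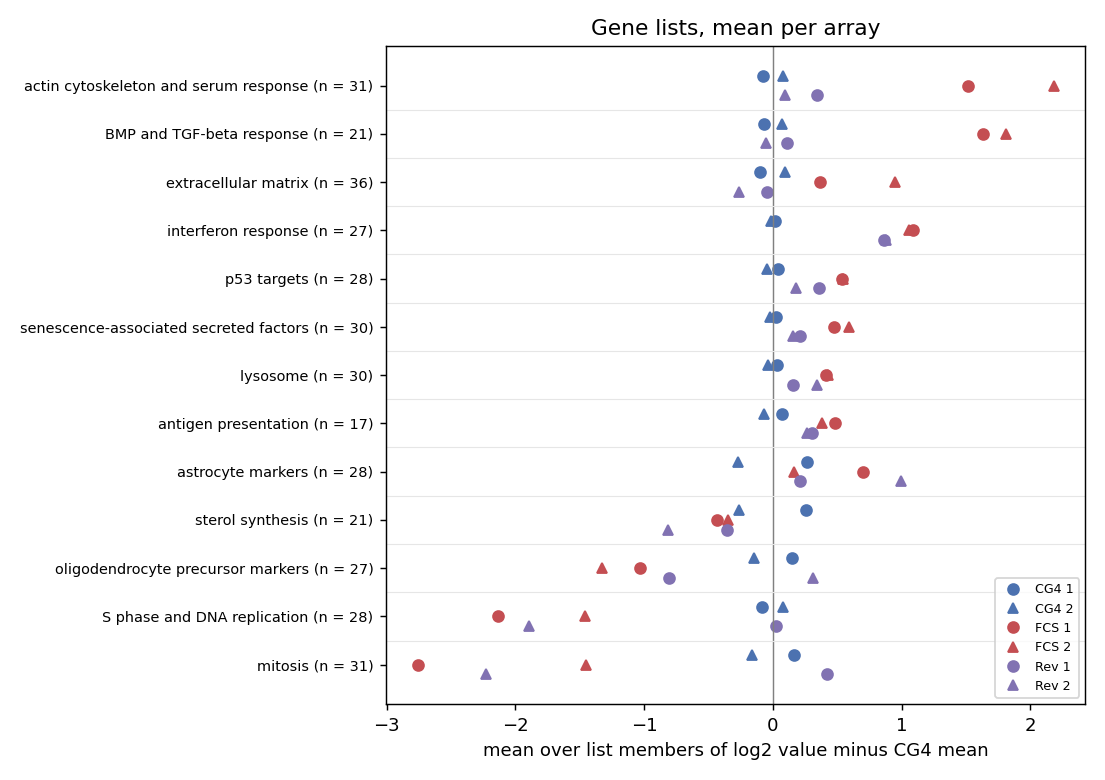
Mean log2 difference from the CG4 mean (horizontal axis) of 13 gene lists in each of the 6 arrays, coloured by group. The interferon list lies at 0.87 and 0.88 in the Rev arrays, the BMP and actin lists lie near CG4 in both, and the S phase and mitosis lists divide the Rev arrays.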

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

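All tests of the patterns in this part were chosen after the results they bear on had been seen.

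Probe sets that carry no single gene name were left out of the comparisons above, and some of them differed in FCS minus CG4. Of 3706 such probe sets among the 27022 kept, 155 were called higher and 178 lower at the same threshold. The largest rise among them was a log2 change of 5.34 (adjusted p = 0.00792) and the largest fall -4.15 (adjusted p = 0.00554). The array annotation pairs these probe sets with no gene or with several, so they are not named.

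The Rev arrays divided on the S phase, mitosis and oligodendrocyte precursor lists. A wrong label on 1 of them is argued against, since the interferon list of the lower Rev array lay 0.853 above the higher CG4 array, where the CG4 arrays differed by 0.0278, and the BMP list of the lower FCS array lay 1.52 above the higher Rev array, where the FCS arrays differed by 0.185. Degraded RNA in Rev 2 stays open, since its 3' minus 5' difference was the highest of the 6 arrays for actin (1.38) but not for Gapdh (1.56, with 1.41 to 1.66 in the others). The data are consistent with each Rev culture having come from the FCS culture of the other number, since all 4 of Xist, Eif2s3y, Kdm5d and Uty differed between the Rev arrays opposite to the FCS arrays. Xist differed by -0.93 for FCS 2 minus FCS 1 and by -1.21 for Rev 1 minus Rev 2, and Uty by 1.01 and 1.31, but transcripts that follow the mix of female and male pups move together, so the 4 weigh little more than 1. That both Rev cultures kept the state of those FCS cultures on the mitosis, S phase and precursor lists is argued against. The FCS arrays differed by 1.31, 0.68 and 0.29 on these lists, and the Rev arrays by 2.65, 1.92 and 1.12. Rev 1 lay 1.87, 1.49 and 0.52 above FCS 2, and the precursor list lay 1.34 higher in Rev 2 than in FCS 1. On the mitosis and S phase lists, however, Rev 2 lay only 0.53 and 0.25 above FCS 1, within the difference between the FCS arrays. For Rev 2 a kept state of the cell cycle genes thus stays open. A true difference between Rev cultures was not tested.

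Part of the FCS response was kept in Rev while other parts returned toward CG4. A mixture of responding and non-responding cells would leave 1 share of every change on the linear scale, but the median share of the 14 called interferon genes exceeded that of the 18 called actin genes by 0.453 in Rev 1 (0.536 against 0.0840) and by 0.476 in Rev 2 (0.497 against 0.0207). From 1 array of each group the difference lay between 0.441 and 0.624 over 8 choices, a range of 0.183. This spread replaced a permutation of genes, since genes of a pathway move together and the lists had been seen to differ. Chance values of the shared CG4 arrays alone are argued against as the whole cause, since 53 of the 87 kept genes differed from CG4 by more than 0.94, the half-difference between the CG4 arrays that 1 in 1000 genes exceeds, which is 13 of all genes tested. The 13 leaves out the error of the Rev mean, and 903 genes differed over 2-fold between the Rev arrays against 279 in CG4. The kept genes were also selected by their Rev values, so chance in CG4 and Rev together stays open. This test replaced a comparison with simulated data, and it leaves the other 34 kept genes open. That serum left a lasting change in part of its targets remains a hypothesis, and so does a slower return of the interferon genes, since the labels give no times. A slower return does not cover the interferon genes that lay above their FCS level in both Rev arrays. Their linear shares in Rev 1 and Rev 2 were 1.84 and 1.49 for Trim30a, 1.84 and 1.91 for Usp18, and 1.18 and 1.42 for Rtp4. The other called interferon genes lay under 1 in both, save Ifi27 with 0.83 and 1.05.

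In the actin cytoskeleton, BMP and TGF-beta response and matrix lists, 18 of 31, 11 of 21 and 7 of 36 genes rose in FCS, and 1, 0 and 1 fell. These list calls did not hold with an estimated correlation. The rises might reflect other cells growing in serum. Fibroblasts are argued against as the source. Among their abundant transcripts Col1a1, Col1a2, Col3a1, Dcn and Lum the largest change was 0.435, against a median of 1.80 for the actin list. Pericytes stay open, since none of these 5 was chosen as a pericyte transcript. A first form of this test, that all 5 stay under the filter in both FCS arrays, was met by 3 and was replaced because Col1a2 and Dcn lay over it in every group, and Ogn, Pdgfrl and Foxc1 from the marker list did rise. For astrocytes 57.1% of the marker list had higher means in FCS, 16 of 28, which decides nothing, since the members moved in both directions. In limma 1 of them was called higher and 2 lower, and 5 and 2 in the fit of the 4 CG4 and FCS arrays. A direct response of the precursor cells to serum was not tested apart from these.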

How the results depend on the processing

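Array weights, the block with crossed Rev numbers and the counts without cell cycle genes were chosen after the data were seen, and the other alternatives were planned. Rev minus CG4 gave 0 calls in limma under every setting run, with 885 to 2766 genes or probe sets at an unadjusted p under 0.05, and so did the overlap with FCS minus CG4. Counts of genes called in FCS minus CG4, in Rev minus FCS and called back stayed within 1.5 times 1739, 355 and 342 under quantile normalization, centring, both other filters, means over probe sets, the trend and robust model, and without the S phase and mitosis lists. Under the centring and quantile scalings 59.3% and 57.3% of FCS minus CG4 calls were higher, against 58.0%, and with only the 4 arrays compared 49.8%.

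With every probe set on its own the counts were 2892, 587 and 567, since more features were tested. With only the 4 arrays compared they were 2721, 62 and 59, and with array weights 2772, 301 and 296. These fits give the divided Rev arrays less or no part in the spread of FCS minus CG4, and both held all 1739 genes. A replicate block gave 684, 0 and 0 (1916 at an unadjusted p for Rev minus FCS), and the block with the Rev numbers crossed gave 2608, 718 and 654. Deviations of paired arrays correlated across genes at 0.146 for CG4 with FCS, -0.265 for CG4 with Rev and -0.555 for FCS with Rev. Equal numbers thus varied together in CG4 with FCS, and opposite numbers where Rev was one of the pair. The crossed block was chosen from these deviations, which it absorbs. A change of at least 2-fold left 1137, 334 and 312, and an adjusted p under 0.01 left 394, 0 and 0, as fewer genes pass a stricter threshold. Leaving out each array gave 263 to 2715, 0 to 556 and 0 to 517, the 0 without FCS 2 (1317 at an unadjusted p). The cause of these ranges was not tested beyond the fewer arrays, and a lone array was assumed to vary like the other groups.

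Lists called in FCS minus CG4, Rev minus CG4 and Rev minus FCS numbered 11, 9 and 8. With every probe set they were 13, 13 and 15, with an estimated correlation 0, 0 and 0, with directional fry 6, 1 and 3, and with mixed fry 21, 11 and 18. The estimated correlation was 0.941 for S phase and 0.959 for mitosis. For the BMP, secreted factor and neural stem cell lists it was 0.0092, -6e-04 and 0.0085, under the preset 0.01. Correlation between genes thus does not explain why the calls of the latter lists ended. Directional fry called, among others, BMP in FCS minus CG4 and Rev minus FCS (adjusted p = 0.00900 each). It also called interferon in FCS minus CG4 and Rev minus CG4 (0.00900 each). The cause was not tested further, but fry does not compare a list with other genes. Among 432 list tests without 1 array, 405 kept their side of the threshold, 11 lost a call, 12 gained one and 4 reversed. Over those fits the S phase median ran from -1.65 to -0.024 in Rev minus CG4 and from -0.089 to 1.85 in Rev minus FCS, and the mitosis median from -2.34 to 0.46 and from -0.21 to 2.68, because the Rev arrays differ. The filter at the 60th percentile ended the Rev minus FCS calls of p53 targets and of secreted factors and added 4 list calls. Among 1458 tests of named genes without 1 array, 1025 kept their side of the threshold, 409 lost their call, 24 gained one and 0 reversed. Of 243 tests of named genes, 36 lost and 6 gained a call with 4 arrays, 79 lost it with the replicate block, and 16 gained and 0 lost one with the crossed block. Ccnd3 was not called with means over probe sets (adjusted p = 0.104, from 0.0178 to 0.188 over its alternatives). Probe sets under the filter were tested only in the fit without a filter.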

Other observations

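The comparisons in this part were chosen after the values had been seen. Of the 14 interferon genes that rose in FCS, 0 were called back in Rev minus FCS in limma, while 6 were lower in Rev at an unadjusted p under 0.05. Of the 18 actin and serum response genes that rose 9 were called back, with 17 lower at an unadjusted p, and of the 11 BMP and TGF-beta genes 10 were, with 11 lower at an unadjusted p. The interferon list had also risen less in FCS, by a median of 0.92 against 1.80 for actin and 1.88 for BMP. In simulated data smaller changes were called less often, 33 of 100 at a log2 change of 1 and 98 of 100 at 2. Fewer calls back of interferon genes could thus also come from smaller changes. Genes of a pathway move together, so the counts of a list are not independent, and without FCS 2 limma called back 0 genes of any list. The comparison was made with 2 Rev arrays that were close to each other on all of these lists, with means against CG4 of 0.11 and -0.05 for BMP and of 0.34 and 0.10 for actin. Smooth muscle actin (Acta2) stood at 10.18 ± 0.10 in Rev (n = 2), lower than the 12.06 ± 0.52 of CG4, with an adjusted p of 0.220 for that difference.

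The first principal component held 61.4% of the variance across arrays and separated the groups, with CG4 at -42.4 and -42.2, FCS at 49.4 and 51.0 and Rev at -15.9 and 0.12. The arrays of a group lay apart mainly on the second, which held 19.6%, with Rev 1 at -17.0 and Rev 2 at 41.8. Astrocyte markers averaged 0.21 in Rev 1 and 0.999 in Rev 2 against the CG4 mean, 0.70 in FCS 1 and 0.16 in FCS 2, and 0.27 and -0.27 in the CG4 arrays. Microglial transcripts (Aif1, C1qa, Cx3cr1 and Tyrobp) lay under the filter in all 6 arrays, with highest values from 4.85 for Aif1 to 5.63 for C1qa.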
